A study of Mus musculus with 6 samples.

How the data were processed

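RNA from whole sciatic nerves of 10-month-old mice was labelled with the Affymetrix WT kit and hybridised to 1 whole-transcript mouse array per sample, per the labels, with 3 arrays of wild-type littermates and 3 of Srebf-1c KO mice. The deposited values are probe set intensities on a linear scale. Per the series' design text, the authors used TAC and the Partek software and computed intensities with the Robust Multichip Average (RMA), which corrects the perfect-match signals for background, normalizes them across arrays and combines the probes of a set. Software versions are not given in the sources used here, and the submitters' processing notes name the genome build mm8. That RMA values were put back on a linear scale is inferred from the values, which run from 3.67 to 23738.

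Groups were taken from sample titles, which match the genotype field. The source field of the KO samples reads wild type, against their titles and genotype field. The groups follow the titles, and the level of Srebf1 was lower on all 3 arrays titled KO. The other values of age and tissue were alike for all samples. No pair of arrays held the same values: the largest share of identical probe set values in a pair was 0.117%.

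Log2 was taken with no pseudocount. Probe sets were named through the platform annotation: of 41077, 23521 carried 1 gene symbol, 1814 several and 15742 none. Of the 23521, 23328 matched a RefSeq gene of GRCm38.p6 by Entrez identifier, and no symbol needed an update. Probe sets with several or no symbols were left out of the tests, and 1082 genes with several probe sets were represented by the one with the highest mean over the 6 arrays. This left 22180 genes. Dim genes were not filtered. The build in the notes differs from that of the gene table, so no coordinates are given, and the table served for names and for which genes are neighbours.

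Each gene was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as KO minus wild type, with a two-sided moderated test and Benjamini-Hochberg adjustment over 22180 genes. Values with ± are standard errors of log2 fold changes from this fit, or SDs where stated. The criterion of the study, an unadjusted ANOVA p under 0.05 with a fold change of at least 1.5, was applied to the moderated p, with the ANOVA as an alternative. Of 32 gene lists, covering lipid and energy metabolism, stress, inflammation, matrix, clock, immediate early and sex-linked genes and cell types of nerve and nearby tissue, 30 had at least 5 measured members. They were tested with camera at a preset correlation between genes of 0.01 and adjusted over the 30, and also with an estimated correlation and with fry. Camera asks whether a list differs from the other genes, so its direction can oppose a list mean near 0. Groups, tests, lists and most of the alternatives were fixed before the data were examined. Pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 on Python 3.11.15 were used for joins and plots.

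The genes named were Srebf1 and Srebf2, the 12 with the largest rise and the 12 with the largest fall among genes past an adjusted p of 0.05, and up to 4 members of each list with the smallest p. Where fewer than 12 passed, the rest were filled by size from genes with an unadjusted p under 0.05, at least 1.5-fold change and no overlap of the groups. Predicted and clone genes, olfactory and vomeronasal receptors, antigen receptor segments and RNA genes with the prefixes Mir, Snor, Rnu or n-R were not named, which left out 62 higher and 48 lower genes and kept 48 and 49 to choose from.

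The procedure was tested on simulated data in which 3 arrays against 3 were drawn for the 22180 genes 20 times. It called 7.01% of genes changed 1.5-fold, 44.7% of those changed 2-fold and 86.3% of those changed 4-fold, with 5.05 unchanged genes called per simulation. The criterion of the study took 49.3%, 93.3% and 99.1% of these and 296.8 unchanged genes per simulation. A list shifted by 0.3 on the log2 scale was called in 20 of 20 simulations, and 3 of 580 unshifted lists were called, with genes drawn as uncorrelated.

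Alternatives were a replicate block, the methods' ANOVA, an intensity trend with a robust prior, array weights, leaving out the dimmest 25% or 50% of genes, repeating quantile normalization, bringing arrays to 1 median, averaging the probe sets of a gene, testing every probe set, an adjusted p limit of 0.10, a fold limit of 2, other set tests and leaving out each array. Added after seeing the data were the muscle and the adipocyte score as covariates, the respiratory list without Cox7b, the liver X receptor list without Srebf1 and the adjusted p of Srebf1 over every probe set.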

Results

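Gene expression was measured in the whole sciatic nerve of 10-month-old mice that lack Srebf-1c and of wild-type littermates. Srebf-1c is the product of Srebf1 known as a transcription factor that drives genes of fatty acid synthesis, and the sciatic nerve is a large peripheral nerve of the leg whose axons are wrapped by Schwann cells, many of which make myelin. Each of the 6 samples, 3 per genotype, was hybridised to 1 Affymetrix whole-transcript array. Median intensity over 41077 probe sets was 118, 117.6 and 115.5 on the wild-type arrays and 121.2, 118.9 and 122.6 on the Srebf-1c KO arrays, and 22180 genes were tested. Precision is limited by the number of arrays. The labels number the samples of each genotype from 1 to 3 but do not say that each came from a different mouse, so p-values measure the spread between these samples, which may be partly technical.

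Pairs of arrays correlated at r = 0.9694 to 0.9855 across probe sets, which are not independent replicates, and pairs of the same genotype did not stand apart from mixed pairs: wild-type replicate 3 and KO replicate 2 reached r = 0.9825. The first principal component held 33.6% of the variance and placed wild-type replicate 1 at -31.3 with KO replicates 1 and 3 at -19.2 and -16.3, against 14.7 and 28.8 for wild-type replicates 2 and 3 and 23.3 for KO replicate 2. It did not separate the genotypes. Markers of tissue next to the nerve differed widely between arrays. The adipocyte score, the mean over 18 adipocyte genes of the log2 intensity minus the gene's mean over 6 arrays, was -0.75, 0.0014 and 1.21 in wild type and -0.70, 1.18 and -0.95 in KO. The skeletal muscle score over 20 genes was 0.79, -0.89 and -0.23 in wild type and 0.36, -0.35 and 0.32 in KO. As lists, adipocyte genes had a mean log2 fold change of -0.31 (camera adjusted p = 0.691) and muscle genes of 0.22 (adjusted p = 0.112), and neither list passed the test. The adipokine gene Retn had a log2 fold change of -1.36 ± 0.97 (SE) and the fast myosin heavy chain gene Myh2 of 1.13 ± 0.85. Without KO replicate 2 the adipocyte list passed the test with a mean of -0.98 and the muscle list with a mean of 0.45, and without wild-type replicate 1 they passed with means of -0.76 and 0.67. Directions turned too: the muscle mean was -0.17 without wild-type replicate 2, and the adipocyte mean was 0.22 without wild-type replicate 3 and 0.091 without KO replicate 3.

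Srebf1, the targeted gene, was lower on each KO array than on every wild-type array. Its log2 intensity was 9.53, 9.55 and 9.70 in wild type (9.59 ± 0.10, SD, n = 3) and 8.11, 8.06 and 8.04 in KO (8.07 ± 0.04, SD, n = 3). It fell by 1.52 on the log2 scale (SE 0.11), to 0.348 of the wild-type level, with a limma adjusted p = 0.0497. The single probe set of Srebf1 was measured for the gene as a whole, which also makes the 1a form, and where its probes lie relative to the deleted part is not known here. Srebf2, the relative known for driving cholesterol synthesis genes, had a log2 fold change of -0.15 ± 0.13 (SE) and did not pass the test (adjusted p = 0.905). Adjusted over all genes, the Srebf1 call sits close to the threshold. With each array left out in turn the log2 fold change stayed between -1.56 and -1.47. The adjusted p, from fewer arrays, rose to between 0.255 and 0.764. It also missed 0.05 with the arrays brought to 1 median (adjusted p = 0.0842).

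**Figure D1:**
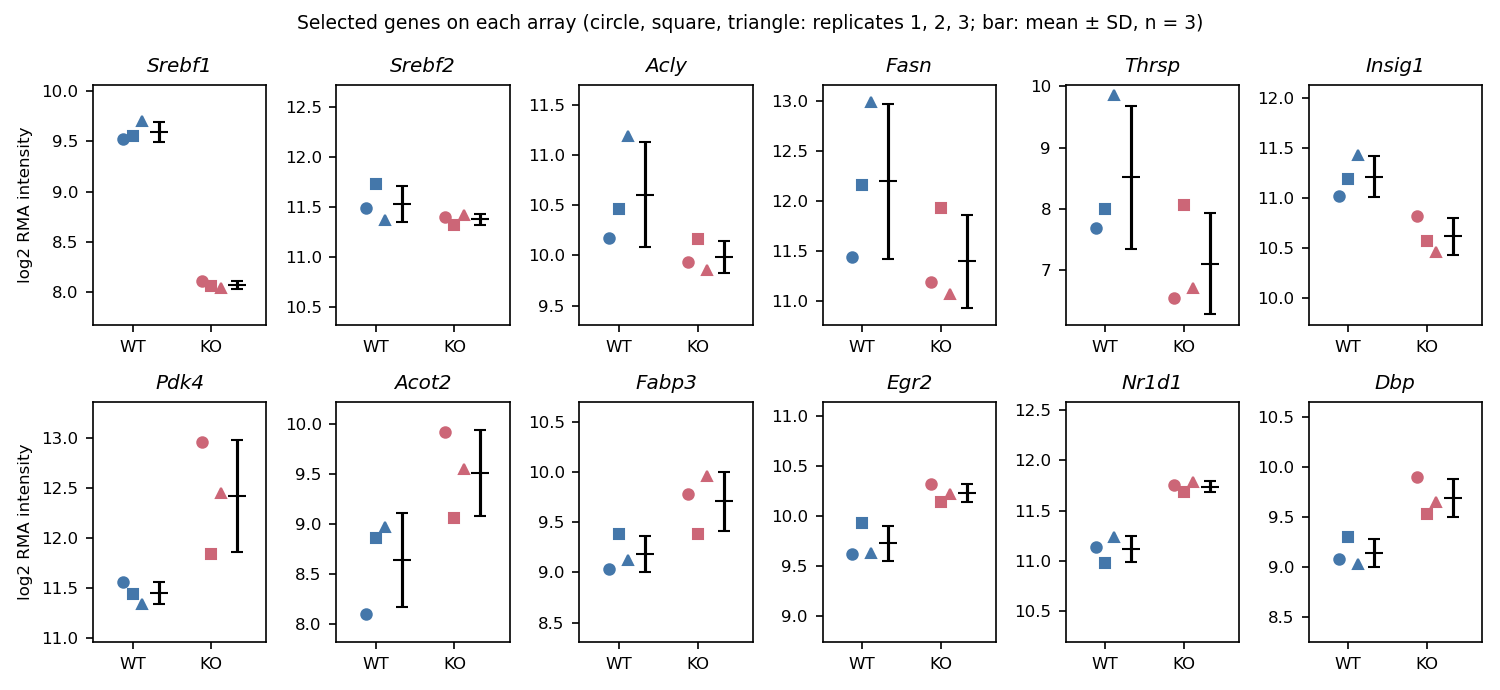
Log2 RMA intensity of 12 genes on each array, with wild type in blue and Srebf-1c KO in red, replicates 1 to 3 as circle, square and triangle, and the mean with SD (n = 3) as a black bar. Srebf1 sits between 8.04 and 8.11 on the KO arrays and between 9.53 and 9.70 on the wild-type arrays, while Fasn and Thrsp spread widely among the wild-type arrays.

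Srebf1 was the 1 gene past an adjusted p of 0.05 in limma, and the next smallest adjusted p was 0.796. At an unadjusted p under 0.05 there were 1293 genes, against 1109 expected by chance. The criterion given with the study, an unadjusted p under 0.05 and a fold change of at least 1.5, was met by 265 genes in limma, 142 higher and 123 lower in KO. In simulated data 296.8 unchanged genes per simulation met it. Those genes were drawn as uncorrelated, so this number is not a chance level for the real arrays. Other splits of the real arrays into 3 and 3 gave from 96 to 865 genes. With the unmoderated test that the study's criterion names in place of limma's it was met by 138 genes. With the arrays brought to 1 median the split was 188 higher and 101 lower, and after quantile normalization it was 122 higher and 142 lower, so which direction held more genes depended on the scaling. Of the 265 genes, 172 had a mean intensity in the dimmer 50% of genes, and 89 genes were left when those were not tested. Without wild-type replicate 1 the count was 435, without wild-type replicate 3 it was 488 and without KO replicate 2 it was 552. The 3 KO values lay all above or all below the 3 wild-type values in 12.3% of genes, where chance gives 10%.

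None of the other genes named by size of change passed the adjusted test (adjusted p of 0.796 or more). Among those higher in KO, Cox7b, a subunit of cytochrome c oxidase, had a log2 fold change of 1.83 ± 0.30 (SE), but its other, dimmer probe set gave -0.29. The ribosomal protein gene Rpl9 stood at 1.54 ± 0.32 (SE), with -0.11 at its other probe set. Hif3a, a member of the hypoxia-inducible factor family, stood at 1.10 ± 0.23, and Pdk4, the kinase that shuts off pyruvate dehydrogenase, at 0.97 ± 0.27. The guanylate-binding protein gene Gbp10 stood at 1.04, the sodium-proton exchanger gene Slc9a3 at 0.91, the ornithine decarboxylase antizyme gene Oaz1 at 0.87 and Acot2, a mitochondrial acyl-CoA thioesterase, at 0.86. The rest were Zfp972 at 1.48, AB010352 at 1.40, Zfp932 at 0.95 and Ceacam14 at 0.86. Rpl9, Gbp10, Zfp972, Zfp932, Ceacam14 and Cox7b belong to families of close relatives or have pseudogenes, so their probe sets may also measure those.

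After Srebf1, the largest fall among the genes named by size was that of Ptcd3, which acts in mitochondrial translation, at -1.30 ± 0.44 (SE). The ribosomal protein gene Rpl3 followed at -1.12 ± 0.29. Naming by size needed an unadjusted p under 0.05 and no overlap of the groups, which Thrsp (-1.41) and Retn (-1.36) did not meet. A second probe set of Ptcd3 gave 0.014, and the others of Rpl3 gave 0.0035 and -0.50. Tnfaip6, which binds hyaluronan, stood at -0.98 ± 0.31, Rgs4, a regulator of G protein signalling, at -0.95 ± 0.27, and the small Cajal body RNA gene Scarna6 at -0.93. Several others were dim: the formyl peptide receptor gene Fpr2 at -1.11 lay in the 6.7th percentile of intensity, the natural killer receptor gene Klrc2 at -0.88 in the 3.6th, Slc10a4l at -0.87 in the 3.3rd and Uqcrh-ps1 at -0.90 in the 9.3rd. Nlrp1c-ps stood at -0.99 and Usp17le at -0.94. The pseudogenes and Usp17le, Rpl3 and Klrc2 have close relatives whose transcripts their probes may share.

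Of 30 gene lists fixed from knowledge of nerve, lipid metabolism and cell types, 7 passed camera at an adjusted p of 0.05, 6 with higher and 1 with lower levels in KO. With a correlation between genes estimated from the arrays, 0 of the 30 passed. For the 7 lists the estimate was 0.79 for the respiratory chain, 0.72 for interferon, 0.56 for myelin and 0.39 for cholesterol genes. It was 0.32 for fatty acid oxidation, 0.041 for peroxisome proliferator-activated receptor targets and -0.0087 for clock genes, against 0.01 preset. With an estimated correlation camera also rests on the 4 residual degrees of freedom, which weakens it by construction. For clock genes the unadjusted camera p rose from 0.00071 to 0.022 although the estimate lay below the preset value. A call lost this way thus need not reflect correlation between genes. Fry gave 0 lists moving on balance in 1 direction and 3 with change in either direction, which were circadian clock genes, immediate early genes and the targets of the liver X receptors. The last list holds Srebf1, the gene the KO targets, and without Srebf1 in it 2 lists were left. With array weights the adipocyte (adjusted p = 0.0169), skeletal muscle (0.0407), endothelial (0.00694) and pericyte (0.0169) lists also passed, and without the dimmest 50% of genes the citric acid cycle (0.0118) and skeletal muscle (0.0273) lists did. Beyond Srebf1 itself, no member of a list passed adjusted over all genes tested. For a single list score, 3 arrays against 3 cannot give an exact permutation p below 0.1.

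Genes of cholesterol synthesis and uptake were lower in KO as a list: 15 of 18 measured genes had a lower mean, the mean log2 fold change was -0.16, the median was -0.15, and the list passed camera (adjusted p = 0.0379) but not fry. The call was lost with an estimated correlation (adjusted p = 0.931 with an estimated correlation). Of the 3 KO arrays, 2 had a list score below every wild-type array. Insig1, which holds the SREBP precursors in the endoplasmic reticulum and is itself an SREBP target, stood at -0.60 ± 0.16 (SE). The enzymes Mvd, Lss and Sqle stood at -0.42 ± 0.16, -0.25 ± 0.13 and -0.25 ± 0.13. No member passed adjusted over the list alone. The call did not hold without wild-type replicate 2 (adjusted p = 0.387), wild-type replicate 3 (0.210) or KO replicate 2 (0.159), nor with the adipocyte score (0.0616) or the muscle score (0.148) as a covariate, after quantile normalization (0.0819) or without the dimmest 50% of genes (0.0880).

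Fatty acid synthesis and desaturation genes had 14 of 19 members with a lower mean in KO, a mean log2 fold change of -0.30 and a median of -0.23, which fell just short of the threshold (camera adjusted p = 0.0514, and adjusted p = 0.931 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, stood at -0.63 ± 0.26 (SE), or 0.648 of the wild-type level. Thrsp stood at -1.41 ± 0.63, Acaca, which makes malonyl-CoA, at -0.44 ± 0.21 and its activator Mid1ip1 at -0.27 ± 0.13. Fatty acid synthase, Fasn, stood at -0.80 ± 0.40. It was picked after the values were seen. No member passed adjusted over the list alone. The wild-type scores ran from -0.10 to 0.46 and the KO scores from -0.24 to -0.0053, and 2 of the 3 KO arrays lay below every wild-type array. The highest wild-type score was that of replicate 3, which also had the highest adipocyte score, 1.21. The list passed without wild-type replicate 1 (mean -0.42, adjusted p = 0.00227) and without KO replicate 2 (mean -0.37, adjusted p = 0.0465). The adipocyte list also passed, with lower means in KO, when either of these arrays was left out. These passes thus cannot be told apart from a difference in fat between the groups. Without wild-type replicate 3 the mean was -0.14. With all arrays it passed with an intensity trend (0.0433), array weights (0.0169), quantile normalization (0.0378), arrays at 1 median (0.0248) or the adipocyte score as a covariate (0.0123). It did not pass with the muscle score as a covariate (0.154), without the dimmest 25% (0.0728) or 50% (0.185) of genes, with the mean of probe sets (0.0638) or in fry (0.700). In all it passed in 5 of 12 other settings on all arrays.

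The remaining lipid lists did not pass camera. Triglyceride storage and lipolysis genes, of which 5 are also adipocyte markers, had 12 of 19 members lower and a mean of -0.14 (adjusted p = 0.691), with Plin2, a lipid droplet coat protein, at -0.42 ± 0.20 (SE) and Plin5 at 0.37 ± 0.17. Targets of the liver X receptors had a mean of -0.10 (adjusted p = 0.831), and fry found change in either direction (adjusted p = 5.70e-05). Both values rest on Srebf1, which is 1 of their 13 members and was the 1 past adjusted over the list alone: for the other 12 the mean was 0.019 (camera adjusted p = 0.632) and fry gave 0.843. Abcg5, a sterol transporter, stood at 0.35 ± 0.14. Phospholipid and sphingolipid synthesis genes had a mean of -0.0055 and a median of -0.025 while camera placed them above other genes (adjusted p = 0.691), and Pcyt2, of the phosphatidylethanolamine pathway, stood at -0.36 ± 0.12. Peroxisomal genes had a mean of -0.028 and a median of -0.037, again with camera pointing up (adjusted p = 0.864), and Acaa1b stood at 0.24 ± 0.13. Genes of steroid hormone synthesis and reduction had a mean of -0.019 and a median of -0.036 with camera pointing up (adjusted p = 0.831), and Hsd17b1 stood at 0.25 ± 0.13.

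Target genes of the peroxisome proliferator-activated receptors (PPARs), which govern fat oxidation and storage, were higher in KO as a list. Of 21 measured genes 16 had a higher mean, the mean log2 fold change was 0.25, the median was 0.17, and camera gave an adjusted p = 0.000944. The adjusted p was 0.416 with an estimated correlation, and fry gave 0.700. Pdk4 stood at 0.97 ± 0.27 (SE), 1.96-fold above wild type. Fgf21, a fasting-induced hormone gene that was dim here, stood at 0.60 ± 0.19, Acot2 at 0.86 ± 0.29 and the fatty acid-binding protein gene Fabp3 at 0.53 ± 0.18. Against the direction of the list, 5 members had a lower mean, among them Plin2 at -0.42 ± 0.20. No member passed adjusted over the list alone (smallest adjusted p = 0.116). List scores were -0.28, -0.13 and 0.043 in wild type and 0.11, 0.23 and 0.032 in KO, and 2 of the 3 KO arrays lay above every wild-type array (exact permutation p = 0.2). The list passed camera with each array left out in turn, with means of 0.17 to 0.33 and an adjusted p of at most 0.0262.

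Mitochondrial lists for fatty acid oxidation and the respiratory chain also had higher means in KO and passed camera at the preset correlation. Their scores overlapped between the groups, with an exact permutation p of 0.4 for fatty acid oxidation and 0.5 for the respiratory chain. Of 18 fatty acid oxidation genes, 3 of them shared with the PPAR list, 15 had a higher mean, with a mean log2 fold change of 0.14 and an adjusted p = 0.00533 in camera, against an adjusted p = 0.931 with an estimated correlation. The electron transfer genes Etfa and Etfdh stood at 0.33 ± 0.16 (SE) and 0.26 ± 0.19, the dehydrogenase gene Acadl at 0.32 ± 0.23 and the thiolase gene Acaa2 at 0.16 ± 0.13. Of 30 respiratory chain genes 24 had a higher mean, with a mean of 0.21 and an adjusted p = 0.00413, against an adjusted p = 0.931 with an estimated correlation. Cox7b passed adjusted over the list alone, and without it, an alternative chosen after seeing the data, the mean was 0.15 (adjusted p = 0.0105). Cox5b stood at 1.05 ± 0.37, Uqcrb at 0.58 ± 0.25 and cytochrome c, Cycs, at 0.60 ± 0.30. Scores of the respiratory list followed the muscle scores across arrays in part, with KO replicate 1 highest at 0.48 and wild-type replicate 2 lowest at -0.37. Neither call held without wild-type replicate 2 (adjusted p = 0.119 for fatty acid oxidation and 0.396 for the respiratory chain, where the mean was 0.071) or without KO replicate 1 (0.412 with a mean of 0.031, and 0.813 with a mean of 0.020), and the respiratory call was lost with the muscle score as a covariate (0.0895).

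Citric acid cycle genes had 18 of 22 members higher and a mean of 0.082 but did not pass (adjusted p = 0.0774). Pcx, which makes oxaloacetate, stood at -0.55 ± 0.35 (SE) and Dld at 0.27 ± 0.18. The list passed without wild-type replicate 1 (mean 0.21) and without KO replicate 2 (mean 0.20), and its mean was -0.092 without wild-type replicate 2 and -0.083 without KO replicate 1. Glycolysis genes went both ways, with a mean of 0.025 (adjusted p = 0.691): the liver-type phosphofructokinase gene Pfkl stood at -0.46 ± 0.12 and the phosphoglycerate mutase gene Pgam1 at 0.53 ± 0.15.

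Markers of myelin and myelinating Schwann cells were slightly higher in KO as a list, with 14 of 19 measured genes higher, a mean log2 fold change of 0.11, a median of 0.083 and a camera adjusted p = 0.0165. The adjusted p was 0.931 with an estimated correlation. Egr2, the transcription factor of the myelinating state, stood at 0.50 ± 0.13 (SE), with all KO values above all wild-type values. The sphingolipid hydroxylase gene Fa2h stood at 0.35 ± 0.16, Cldn19 at 0.30 ± 0.18 and Ndrg1 at 0.16 ± 0.14. No member passed adjusted over the list alone, and 1 of the 3 KO arrays lay above every wild-type array. The call was lost without wild-type replicate 1 (adjusted p = 0.216, mean 0.066), wild-type replicate 3 (0.203, mean 0.064), KO replicate 1 (0.0547) or KO replicate 3 (0.179), with the adipocyte score as a covariate (0.0620) and after quantile normalization (0.139). Markers of immature and repair Schwann cells had a mean of -0.030 and a median of -0.050 while camera pointed up (adjusted p = 0.897). Of these, Id4 stood at -0.39 ± 0.18 and the low-affinity neurotrophin receptor gene Ngfr at -0.26 ± 0.14. Sox2 stood at 0.34 ± 0.22 and Jun at 0.22 ± 0.17.

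Circadian clock genes differed between the groups. Nr1d1, a repressor of the clock loop, stood at 0.62 ± 0.12 (SE), Per1 at 0.52 ± 0.13, Dbp at 0.55 ± 0.15, Nr1d2 at 0.52 ± 0.14 and Ciart at 0.65 ± 0.19, and for each the 3 KO values lay above the 3 wild-type values. These 5 of 16 measured genes rose, adjusted over the list alone (smallest adjusted p = 0.0188), and none of them passed adjusted over all genes. As a list, 11 of 16 were higher, with a mean log2 fold change of 0.15 and a camera adjusted p = 0.00533, which was 0.416 with an estimated correlation. All 3 KO scores lay above the wild-type scores (exact permutation p = 0.1, the smallest possible). Arntl, the activator of the loop, stood at -0.27 ± 0.13 and Nfil3 at -0.50 ± 0.27. Ciart, Arntl and Nfil3 were picked after the values were seen. Without wild-type replicate 2 the list missed the threshold (adjusted p = 0.0804). Immediate early genes, which respond within minutes to handling or activity, had a mean of -0.14 and did not pass as a list (adjusted p = 0.269), but fry found change in either direction (adjusted p = 0.0268, or 0.0401 with Srebf1 taken out of the liver X receptor list): Atf3 stood at -0.59 ± 0.16, Egr1 at -0.75 ± 0.29 and Fos at -0.39 ± 0.16, and Ccn1 at 0.39 ± 0.14.

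**Figure D2:**
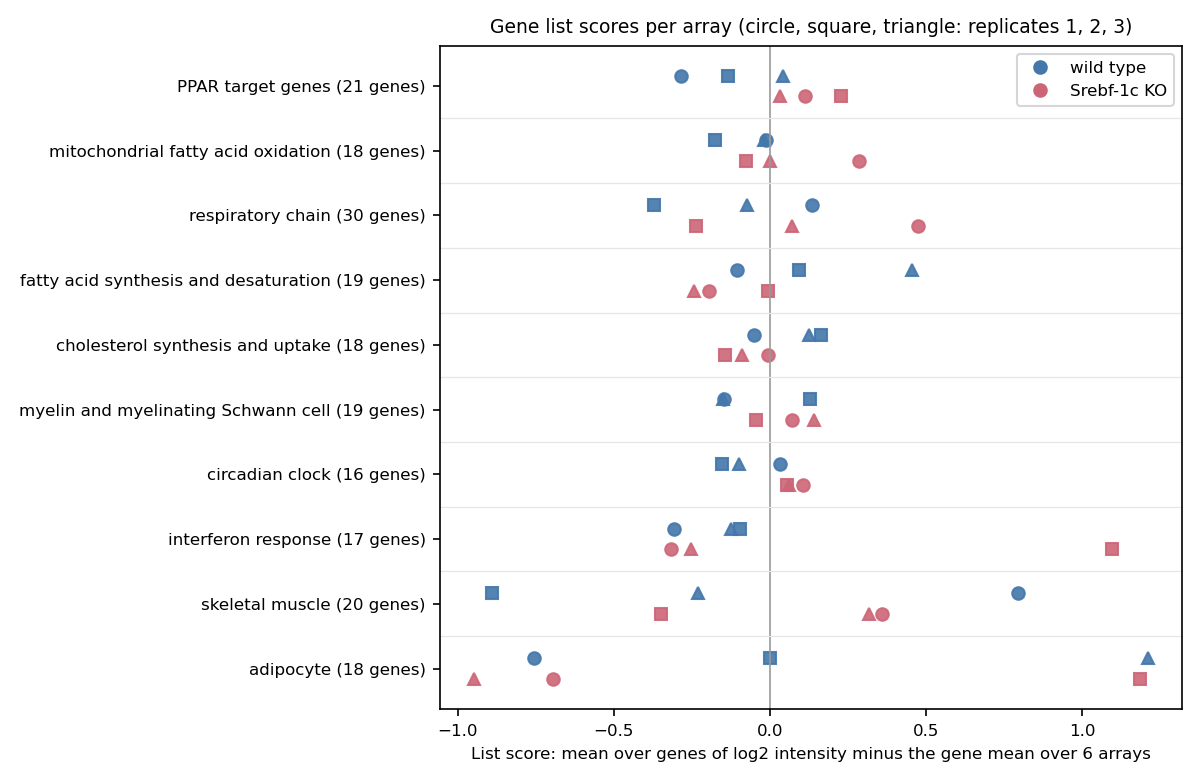
Scores of 10 gene lists on each array, as the mean over a list's genes of log2 intensity minus the gene's mean over 6 arrays, with wild type in blue, Srebf-1c KO in red and replicates 1 to 3 as circle, square and triangle. The interferon score of KO replicate 2 lies at 1.10, far from the other arrays, and the adipocyte and muscle scores spread more within a genotype than between genotypes.

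Interferon response genes passed as a list, with 15 of 17 members higher in KO and a mean log2 fold change of 0.35 (camera adjusted p = 0.00746, and adjusted p = 0.931 with an estimated correlation), while 1 of the 3 KO arrays lay above the wild-type arrays. The list score was 1.10 in KO replicate 2 and -0.32 and -0.25 in the other KO replicates, against -0.31, -0.096 and -0.13 in wild type. Without KO replicate 2 the mean was -0.11 and the call was lost (adjusted p = 0.255), as it was without wild-type replicate 1 (0.0723) and with array weights (0.221). Ifit1, an antiviral protein gene, stood at 0.76 ± 0.54 (SE), Irf9 at 0.45 ± 0.26, Xaf1 at 0.43 ± 0.22 and Ifit3 at -0.28 ± 0.19. Inflammatory cytokine and chemokine genes had 15 of 20 members lower and a mean of -0.15 and did not pass (adjusted p = 0.120), with Cxcl10 at -0.64 ± 0.22 and Ccl2 at -0.54 ± 0.20. They passed without KO replicate 2 (adjusted p = 0.0421).

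Markers of blood vessels had lower means in KO without passing, and their list scores overlapped between the groups. Of 15 endothelial genes 14 had a lower mean, with a mean log2 fold change of -0.20 (adjusted p = 0.0790), and Kdr, a receptor for vascular endothelial growth factor, stood at -0.47 ± 0.20 (SE). Pericyte and smooth muscle genes had a mean of -0.38 (adjusted p = 0.167), with Notch3 at -0.51 ± 0.27. Without KO replicate 2 both passed (means -0.35 and -0.62), as they did without wild-type replicate 1 (means -0.29 and -0.60). Neither passed with any other array left out, where means came as near to 0 as -0.047 and -0.11 (camera adjusted p up to 0.907). Endothelial genes also passed with the arrays brought to 1 median (adjusted p = 0.0481). Macrophage markers had a mean of -0.072 (adjusted p = 0.825) and passed without KO replicate 2 (mean -0.37). Of these, Tyrobp stood at -0.33 ± 0.31, Aif1 at -0.22 ± 0.13, Cd163 at 0.52 ± 0.43 and Fcgr1 at 0.27 ± 0.26. Mast cell markers had a mean of 0.069 (adjusted p = 0.269) and passed without KO replicate 1 (mean 0.21), and Kit stood at 0.36 ± 0.15. Lymphocyte markers were dim and had a mean of 0.014 (adjusted p = 0.644). Fibroblast markers had a mean of -0.032 and a median of -0.045 with camera pointing up (adjusted p = 0.691), and passed upward without KO replicate 1 (mean 0.16). Perineurial markers had a mean of -0.14 (adjusted p = 0.758). Extracellular matrix genes had 19 of 24 members lower and a mean of -0.078 (adjusted p = 0.831), with the crosslinking enzyme gene Lox at 0.47 ± 0.23. They passed downward without wild-type replicate 1 (mean -0.24) and without KO replicate 2 (mean -0.25).

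Stress lists did not pass. Endoplasmic reticulum stress genes had a mean of -0.056 (adjusted p = 0.691), and Chac1, which breaks down glutathione, stood at 0.75 ± 0.25 (SE). Oxidative stress genes had a mean of -0.059 (adjusted p = 0.825), with the metallothionein genes Mt2 and Mt1 at 0.42 ± 0.13 and 0.38 ± 0.15, and Gpx4, which reduces lipid peroxides, at -0.28 ± 0.11. No member of either list passed adjusted over the list alone. The lists of sex-linked and erythroid genes had too few measured members for a set test. The female-specific transcript Xist was dim in both groups (log2 5.59 ± 0.25 in wild type and 5.69 ± 0.20 in KO, SD, n = 3), and the Y-linked genes Uty, Kdm5d and Eif2s3y had means of 8.92 to 9.84. Of the erythroid genes, Slc4a1 stood at -0.40 and Epb42 at 0.046.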

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

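The covariates, the lists without Cox7b or Srebf1 and the value of Srebf1 over every probe set were chosen after seeing the data. The log2 fold change of Srebf1 kept its direction in every setting run, and its adjusted p passed 0.05 with all 6 arrays except with the replicate block (-1.52, adjusted p = 0.713), in the methods' ANOVA (-1.52, 0.308), with arrays at 1 median (-1.49, 0.0842), over every probe set (-1.52, 0.190) and with the muscle (-1.52, 0.223) and adipocyte (-1.51, 0.174) covariates. In these settings 0 genes passed. With each array left out the Srebf1 value ran from -1.56 to -1.47 and missed the threshold, and the count of genes ran from 0 to 1, the 1 gene being Vmn1r157 without KO replicate 2, named because it was the only one. Fewer arrays or fewer residual degrees of freedom weaken the test by construction. The 265 genes of the study criterion became 138 in the methods' ANOVA, 150 and 89 without the dimmest 25% and 50%, 34 at a fold limit of 2, 1483 over every probe set (17556 of them without a single gene symbol, so not a count of genes), and 231 to 552 with an array left out.

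The 7 gene lists became 11 with array weights, 0 with an estimated correlation, 0 in fry and 3 to 14 with an array left out. The call of PPAR target genes ended with an estimated correlation and in fry, which change the set test and leave the mean of 0.25 as it is, and the mean ranged from 0.17 to 0.33 with an array left out. Fatty acid synthesis genes passed the threshold with the intensity trend (-0.30), array weights (-0.38), quantile normalization (-0.32), arrays at 1 median (-0.27) and the adipocyte covariate (-0.24), in 5 of 12 settings on all arrays, and ranged from -0.42 to -0.14 with an array left out. The cause of these changes was not tested.

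Means of lists that did not pass changed sign, most of them near 0. Array weights gave -0.014 for lymphocytes and -0.0033 for mast cells, and quantile normalization gave -0.031 for lymphocytes and 0.0028 for phospholipid synthesis. Arrays at 1 median gave 0.00125 for immature Schwann cells, 0.0036 for peroxisomal genes, 0.026 for phospholipid synthesis and 0.012 for steroid synthesis. The muscle covariate gave 0.00301 for matrix, 5.21e-05 for macrophages, 0.027 for phospholipid synthesis, 0.054 for fibroblasts, -0.038 for glycolysis and -0.0088 for lymphocytes. The adipocyte covariate gave 0.00143 for triglyceride genes, 0.0575 for macrophages, 0.012 for peroxisomal genes, 0.0082 for phospholipid synthesis and 0.10 for fibroblasts. LXR targets had 0.019 without Srebf1. With an array left out, lists were lower in place of higher without wild-type replicate 2: means ran from -0.12 to 0.16 for glycolysis, -0.092 to 0.21 for the citric acid cycle and -0.088 to 0.091 for lymphocytes (all 3 also lower without KO replicate 1) and -0.17 to 0.67 for muscle. Mast cells (-0.087 to 0.21) were lower without KO replicate 2. Others were higher in place of lower without wild-type replicate 3: -0.24 to 0.056 for LXR targets, -0.41 to 0.17 for triglyceride genes, -0.10 to 0.071 for peroxisomal genes, -0.089 to 0.054 for phospholipid synthesis, -0.11 to 0.018 for endoplasmic reticulum stress, -0.25 to 0.079 for matrix, -0.98 to 0.22 for adipocytes, -0.32 to 0.23 for fibroblasts and -0.37 to 0.18 for macrophages. So were phospholipid synthesis, immature Schwann cells (-0.089 to 0.030), matrix, macrophages, fibroblasts (which then passed, 0.0303) and perineurial cells (-0.29 to 0.026) without KO replicate 1, phospholipid synthesis and immature Schwann cells without wild-type replicate 2, and triglyceride genes, peroxisomal genes, fibroblasts and adipocytes without KO replicate 3. Among named genes, Epb42 ran from -0.071 to 0.22 (negative without wild-type replicate 2 and KO replicates 1 and 3), and negative without KO replicate 1 were Kdm5d (-0.21 to 0.46), Uty (-0.038 to 0.41) and Xist (-0.011 to 0.24). Epb42 was at -0.00047 after quantile normalization. The interferon list, which did pass, ran from -0.11, without KO replicate 2, to 0.60. The cause was not tested.

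The values gave no sign that the replicate numbers pair the samples, though 3 arrays per group cannot exclude a pairing. Deviations from the group means correlated at 0.117, 0.0117 and -0.233 between arrays of the same number, and wild-type replicate 3 matched KO replicate 2 best (0.281). With the replicate block 0 genes passed, 288 met the study criterion, fatty acid synthesis genes did not pass (0.0539) and 9 lists passed, among them the citric acid cycle and skeletal muscle.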

Other observations

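The tests reported here were chosen after the results were seen, except the counts over splits for the study criterion and for gene lists. The slopes on tissue scores below replaced a first test, the KO difference with the tissue score as a covariate, after its results were seen. That test left 3 of 5 cases open: PPAR targets with the muscle score (0.28, 95% interval -0.041 to 0.60) and fatty acid synthesis with the adipocyte (-0.24, -0.53 to 0.052) and muscle scores (-0.26, -0.82 to 0.31). The intervals excluded 0 for PPAR targets with the adipocyte score (0.28, 0.13 to 0.44) and for the phase difference of clock genes with the muscle score (0.65, 0.34 to 0.96).

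Clock genes were compared by phase. The 8 genes that peak with Nr1d1 or near it had a mean log2 fold change of 0.41 (95% interval 0.25 to 0.57), and the 5 of roughly opposite phase, among them Arntl and Nfil3, had a mean of -0.23 with an interval that includes 0 (-0.48 to 0.023), so lower levels of that set were not shown. The difference between both sets was -0.43, -0.29 and -0.24 on the wild-type arrays and 0.44, 0.22 and 0.31 on the KO arrays. Ucp3, a mitochondrial uncoupling protein gene of the PPAR list picked after its value was seen, stood at 0.63 ± 0.29 (SE).

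Of the 10 splits of the 6 arrays into 3 and 3, 2, the real one included, gave at least the 1 gene past an adjusted p of 0.05 that the real one gave, with 1 as the highest other. Counted in the same way, 7 splits gave at least the real 265 genes of the study criterion, with 865 as the highest other, and 7 gave at least the real 7 gene lists, with 19 as the highest other. With 10 splits no share under 0.05 can be reached. The split with 865 genes and 19 lists set wild-type replicate 1 with KO replicates 1 and 3 against the other arrays, which points to a structure of the samples that is not genotype. The same arrays lay on 1 side of the first principal component and had the 3 lowest adipocyte scores.

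The first pattern is lipid metabolism: PPAR target genes passed camera upward but not with an estimated correlation (adjusted p = 0.416), and fatty acid synthesis genes had a mean of -0.30 that did not pass (0.0514). If tissue around the nerve made the whole difference, list scores would follow the tissue score within genotypes at the slope needed. For PPAR targets the slope on the muscle score was -0.129 (95% interval -0.418 to 0.159, against 1.14 needed) and on the adipocyte score 0.116 (0.0299 to 0.201, against -0.813), and for fatty acid synthesis the slope on the adipocyte score was 0.183 (0.0199 to 0.346, against 0.968) and on the muscle score -0.182 (-0.691 to 0.328, against -1.36). The intervals exclude the slopes needed, but a slope needed takes the observed group differences as known. The first test, which keeps the error of the KO difference, left 3 of 5 cases open. For PPAR targets with muscle and for fatty acid synthesis with fat or muscle, tissue as the whole cause thus stays open. For PPAR targets with fat, both tests argue against it. Fatty acid synthesis scores did follow fat in part, and 3 residual degrees of freedom make the intervals rest on few arrays. Loss of Srebf-1c stays open as an explanation that was not tested apart from chance, tissue around the nerve, time of day or feeding.

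The second pattern is the clock. A difference in the time of day of dissection may give it, and would move the opposite-phase genes down. Their mean was -0.231 with an interval that reaches 0.023. The difference between both sets was higher in KO by 0.641 (interval 0.404 to 0.878). An effect of genotype on the clock could give the same directions, so these values cannot tell time of day and genotype apart. Collection times are also not given in the sources used here. The slope of the phase difference on the muscle score was -0.0365 (-0.318 to 0.245, against 2.93 needed), which argues against muscle as the cause. Pdk4 and other PPAR targets are also known to vary with time of day and feeding, so the first pattern shares this open explanation.

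The third pattern is the interferon list. Its mean log2 fold change was 0.35 with all arrays and -0.108 without KO replicate 2, which had the highest score, 1.10. Leaving out the array with the highest score lowers the mean by construction, so this tests no explanation. The scores of KO replicates 1 and 3, -0.32 and -0.25, lay below the wild-type mean of -0.18. The higher list mean in KO thus came from KO replicate 2 and was not shared by the group. Why that sample was high was not tested.

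DNA of the donor strain next to a targeted allele could change neighbouring genes. Of the 100 measured genes nearest Srebf1 in gene order, 50 on each side, 6 had an unadjusted p under 0.05 (6%, exact 95% interval 2.23% to 12.6%), against 5.83% of other genes (Fisher's exact test, two-sided, p = 0.831), and of the nearest 200 it was 17 (8.5%, p = 0.126), which leaves the question open.

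Of 17556 probe sets without a single gene symbol, 1194 (6.8%) met the study criterion, against 1.23% of named probe sets. Of these, 5074 have identifiers below that of the first named probe set, and 537 of them met the criterion (10.6%), 427 higher in KO. The highest count in another split of the arrays was 542. What these 5074 measure is not known here, and control probe sets may be among them, so neither these shares nor the 1483 over every probe set count genes. Their median log2 intensity was 6.7, 7.04 and 6.78 on the wild-type arrays and 7.02, 6.94 and 6.96 on the KO arrays.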
